A study of Rattus norvegicus with 44 samples.

How the data were processed

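RNA of rat gastrocnemius, a calf muscle, was measured on 44 one-colour oligonucleotide arrays, 4 at each of 11 labelled times: a 0 h control group and 10 groups given methylprednisolone (a synthetic glucocorticoid) by constant infusion from an implanted pump, for times from 6 to 168 h. These were 6, 10, 13 and 18 h within the first day, then 24, 36 and 48 h, and then 72, 96 and 168 h. The labels number the rats within each time, and each array was taken as 1 animal. The description of 168 h replicate 4 names rat 1 although its title gives 4, and the title was followed, so the number of animals at 168 h rests on the titles. The descriptions of the 0 h arrays speak of a drug implant in control rats, so what these rats were given is not clear. There was 1 control group, at 0 h, and no vehicle group matched to the later times, so treatment, time since surgery and time of day cannot be separated by the comparisons with control. Another series of single injections named in the study's design text was not analysed here.

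The authors deposited 1 linear signal intensity per probe set and array, made with MAS5 per the submitters' processing notes (its version is not given in the sources used here). A probe set is a group of short oligonucleotides that together measure 1 transcript, and MAS5 reduces their brightness, corrected for mismatch probes, to a single value. The deposited table held 15923 probe sets. The mean intensity after trimming 2% at each end lay between 150.04 and 150.05 on every array, so the arrays had already been scaled to a common level, and the values were used as deposited. The array medians ran from 52.2 to 70.5. In 4 columns the values were rounded to 1 decimal. No detection calls were used. For arrays the number of samples limits the precision, which is 4 per group here. The log2 signals of arrays of one group correlated with each other at 0.894 to 0.959, and no pair of arrays correlated above 0.962.

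Left out were 57 array control probe sets. Of the other 15866, 12783 carried exactly 1 gene symbol in the platform annotation, 312 carried several and 2771 carried none. Symbols were looked up in a newer rat gene table through the gene ID, which gave the symbol of 12748 probe sets, and 35 kept the platform symbol. No gene was named from a probe set with several symbols. No genome build belongs to these values, so no coordinates are given.

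Intensities were log2-transformed without an offset. Probe sets below the 40th percentile of mean log2 signal, which corresponds to an intensity of 42.4, were left out, and 9520 were tested. One linear model with a mean for each of the 11 groups was fitted to all 44 arrays with limma 3.58.1 in R 4.3.3, with moderated variances that follow the mean signal (eBayes with trend) and 33 residual degrees of freedom. All p-values of single probe sets are limma's two-sided moderated tests with Benjamini-Hochberg adjustment over the 9520 probe sets, and the threshold was an adjusted p of 0.05. The comparisons were an F-test of all 10 times against control, the mean of the early window (6, 10, 13 and 18 h, 16 arrays) against control, the mean of the late window (72, 96 and 168 h, 12 arrays) against control, late against early, the times that are multiples of 24 h (24, 48, 72, 96 and 168 h, 20 arrays) against control, and each time against control. Windows are means of group means. Errors of fold changes are standard errors of the fit, and errors of intensities are SDs over 4 arrays.

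A total of 27 gene lists with 594 entries was written before the data were examined, from textbook knowledge of muscle, glucocorticoid action and other cell types that a muscle sample can hold. Of these entries, 499 matched a probe set. For lists, each gene was represented by its brightest probe set, which gave 7045 genes. The 25 lists with at least 5 measured genes were compared with all other genes by limma's camera with a preset inter-gene correlation of 0.01, and again with an estimated correlation. List p-values were adjusted over the 25 lists. Counts of list members refer to adjustment over all 9520 probe sets unless stated as adjusted over the list alone. Several genes stand in more than 1 list.

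The genes named in the text followed a rule fixed together with the lists. For each of the 3 window comparisons it took the 8 higher and the 8 lower genes with the largest change past the threshold, with 1 symbol that is not a clone name and, against control, with every group mean of the window on the same side. It took up to 4 members with the smallest p from each list, the 2 higher and 2 lower genes with the largest change at each time, and 18 genes of prior interest, of which 17 were measured above the filter (Mt1 was not). A gene with several probe sets is given by the brightest one unless the rule picked another. Genes named outside the rule are marked as chosen after their values were seen.

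The functions were tested on simulated arrays with the measured means and SDs, in which 200 of 9520 probe sets were changed. Noise was drawn independently for each probe set and array, so the shares below do not cover variation that probe sets or arrays have in common. For early against control, 44.8% of the 1.5-fold, 80.6% of the 2-fold and 100% of the 4-fold changes were recovered, and 6.25% of the calls were false. For late against control these shares were 41.8%, 82.1% and 100%, with 7.45% false calls. For late against early these shares were 85.1%, 95.5% and 100%, with 2.6% false calls. For 6 h against control they were 20.9%, 61.2% and 97%, with 4.03% false calls.

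Alternatives fixed at the same stage were quantile normalization, centring each array on its median, an offset (the 10th percentile of all intensities) before the log transform, no signal filter, a filter at the 60th percentile, no variance trend, array quality weights, the replicate number or the series of original sample numbers as a block, each array left out in turn, fits of only the 2 groups compared, and for the lists an estimated correlation and the mean of all probe sets of a gene. Added after seeing the data were fits without the 168 h arrays, fits without 4 arrays with a high ratio of 3′ to 5′ signal of the GAPDH control probe sets, comparisons of every pair of groups, and a list of fibroblast markers.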

Results

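The arrays covered gastrocnemius muscle of 4 rats at each of 11 times, from the 0 h control to 168 h of constant methylprednisolone infusion. The design asks how gene expression in muscle moves when the drug is held at a constant supply, and whether the first-day response lasts. RNA integrity was gauged by the log2 ratio of 3′ to 5′ signal of the GAPDH control probe sets. This ratio was above 0.5 on 4 arrays: 0.80 on 0 h replicate 2, 0.52 on 72 h replicate 4, 0.58 on 96 h replicate 4 and 1.43 on 168 h replicate 4. Its group mean was 0.33 ± 0.32 (SD, n = 4) at 0 h, 0.38 ± 0.70 (SD, n = 4) at 168 h and at most 0.21 in the other groups. The same ratio of the beta-actin control probe sets was 0.70, 1.71, 0.55 and 1.07 on 0 h replicates 1 to 4. On treated arrays it was 1.35 on 168 h replicate 4 and otherwise at most 0.75. By this ratio the control arrays lay toward the high end, while the 4 arrays set apart were chosen by GAPDH alone.

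Of the 9520 probe sets tested, 2455 differed from control at some time by limma's F-test. The glucocorticoid-responsive genes Fkbp5 and Ddit4 were past the threshold at every time. Fkbp5, a co-chaperone of the glucocorticoid receptor, went from an intensity of 45.05 ± 9.59 (SD, n = 4) at 0 h to 458 ± 77.5 at 6 h and 571 ± 43.3 at 96 h. Ddit4, an inhibitor of mTOR signalling, went from 37.8 ± 7.16 to 951.5 ± 394 at 6 h and 1163 ± 251 at 96 h. Other genes lay farther from control at 96 h than at 6 h. Col1a1, which codes for a chain of type I collagen, had an intensity of 3034 ± 244 at 0 h, 3299 ± 760 at 6 h and 245.5 ± 36.6 at 96 h. Glul, glutamine synthetase, had 1117 ± 410 at 0 h, 1851 ± 594 at 6 h and 5284 ± 294 at 96 h. The largest group-mean distance from control fell at 96 h for 606 of the 2455 probe sets and at 72 h for 356.

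**Figure D1:**
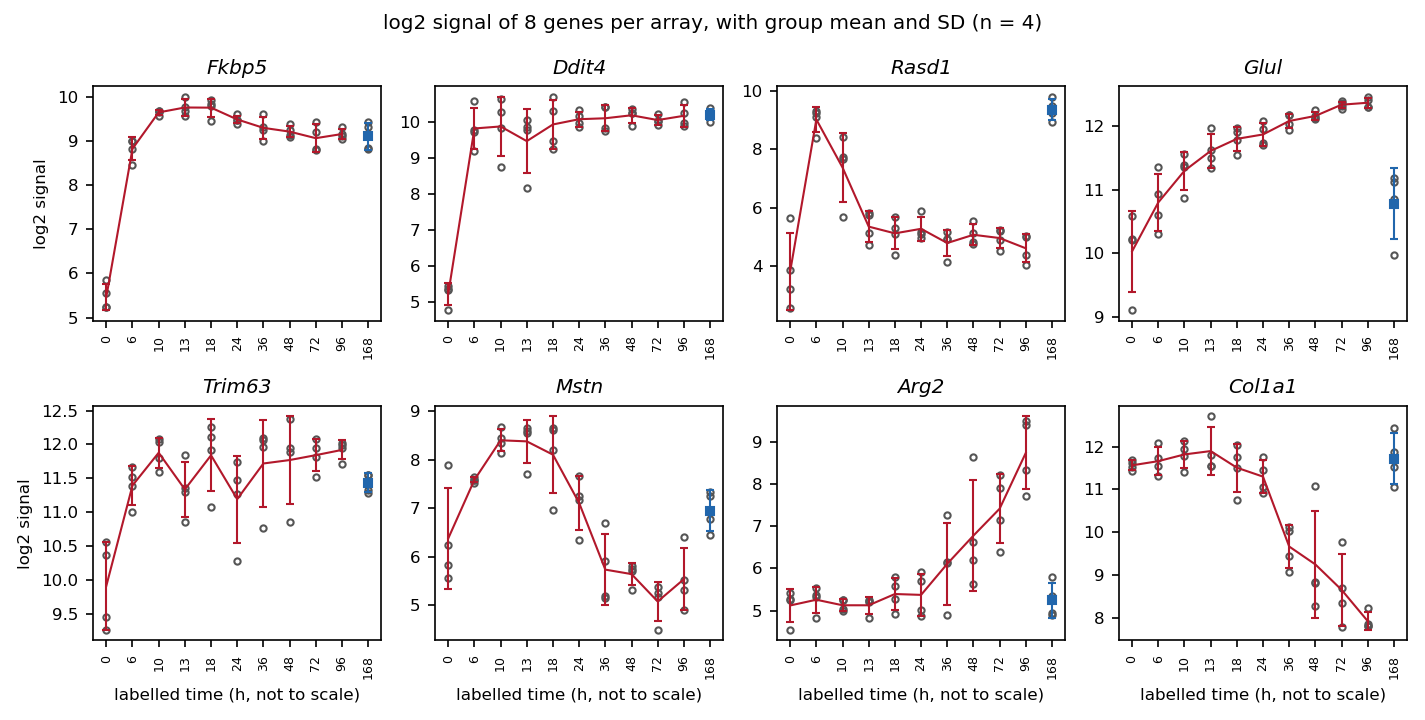
log2 signal (vertical axis) of 8 genes at the labelled times in hours (horizontal axis, not to scale); open circles are single arrays, and lines or squares with bars are the group mean and SD of 4 arrays. Fkbp5 and Ddit4 are high from 6 h on, Col1a1 falls to an intensity of 245.5 at 96 h, and at 168 h (blue) Rasd1, Glul, Arg2 and Col1a1 lie near their 6 h values.

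The early window, 6 to 18 h, was compared with control to describe the first-day response. Ddit4 was 23.3-fold higher (log2 fold change 4.54 ± 0.26 SE) and Fkbp5 16.3-fold higher (4.02 ± 0.13), each above all 4 control arrays on 16 of 16 arrays. Cebpd, a transcription factor, was 4.09-fold higher by its brighter probe set and 17.9-fold by another (log2 4.16 ± 0.88). Errfi1, an inhibitor of the epidermal growth factor receptor, was 9.88-fold higher, the matrix glycoprotein gene Tinagl1 7.9-fold, the Ras-related gene Rasd1 7.49-fold (above all 4 control arrays on 11 of 16), the mitochondrial ribosomal protein gene Mrpl41 7.2-fold and Pfkfb4, an enzyme that sets the level of a glycolytic regulator, 7.02-fold. Lower were the myogenic regulator Myod1 (5.85-fold, log2 -2.55 ± 0.27), the membrane glycoprotein gene Gpnmb (5.34-fold), the kinase substrate gene Marcks (4.59-fold), the secreted phospholipase gene Pla2g2a (4.52-fold), the clock output gene Dbp (3.54-fold), the interferon-inducible gene Ifi27l2b (3.49-fold), Ltbp1, which codes for a binder of latent TGF-beta (3.17-fold), and Sgsm3 (3.09-fold). The highest adjusted p among these was 0.00762, for Pla2g2a, which lay below the control mean on 14 of 16 arrays and did not pass without 0 h replicate 4, where it stood at -1.80 on the log2 scale. The size of some changes depended on 1 array. Early, with each array left out in turn, the larger Cebpd change ran from 3.08 to 4.69 on the log2 scale (farthest without 0 h replicate 2), Rasd1 from 2.49 to 3.51 (0 h replicate 2) and Gpnmb from -3.04 to -1.99 (0 h replicate 3). The log2 signal of Rasd1 on the control arrays ran from 2.56 to 5.64. Within the window its log2 fold change fell from 5.21 at 6 h to 3.57 at 10 h, 1.54 at 13 h and 1.31 at 18 h. At 18 h it did not pass (adjusted p = 0.0595), so the window mean stands for no single time. Folds are also less certain where the dimmer side lies below the intensity of 42.4 used as the filter. Early this held for the control mean of Ddit4 (37.2), Tinagl1 (34.4), Pfkfb4 (19), Rasd1 (14.1) and the larger Cebpd change (13.1), and for the early mean of Sgsm3 (24.7) and Pla2g2a (16.8). The Pfkfb4 values are those of a dimmer probe set. By its brightest one Pfkfb4 was 3.57-fold higher at 6 h, 7.51-fold at 10 h, 6.58-fold at 13 h and 4.87-fold at 18 h.

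Among the genes of prior interest, Trim63, a muscle-specific ubiquitin ligase, was 3.25-fold higher early (log2 1.70 ± 0.24, adjusted p = 2.79e-06), on 16 of 16 arrays. Mstn, myostatin, an inhibitor of muscle growth, was 3.34-fold higher (1.74 ± 0.30, adjusted p = 6.83e-05), and Foxo1, a transcription factor of the atrophy programme, 3.05-fold higher (1.61 ± 0.34). The log2 signal of Mstn on the control arrays ran from 5.55 to 7.89, wider than its shared error shows, and 10 of 16 early arrays lay above all 4 of them. Pdk4, which restrains pyruvate oxidation, was 4.8-fold higher, Per1, a clock component, 4.1-fold, Mt2A, a metallothionein, 3.97-fold (log2 1.24 without 0 h replicate 3), Tsc22d3 (GILZ) 2.77-fold, Glul 2.54-fold and Klf15 2.21-fold. Nr3c1, the glucocorticoid receptor itself, was 1.92-fold lower (-0.94 ± 0.16, adjusted p = 2.93e-05). The ubiquitin ligase gene Fbxo32 (0.75 ± 0.47, adjusted p = 0.346), Odc1 (-0.12 ± 0.13, adjusted p = 0.647), Col1a1 (0.16 ± 0.31) and Col3a1 (0.12 ± 0.23) did not pass the threshold. Igf1 did not pass by its brighter probe set (-0.63 ± 0.40, adjusted p = 0.346) and was lower by the other (-0.70, adjusted p = 0.00377).

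A total of 1126 probe sets passed early against control, 523 higher and 603 lower. Without 0 h replicate 4 the count was 726. With each array centred on its median, 574 were higher and 392 lower, so that the share of higher calls was 59.4% in place of 46.4%.

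By list, direct glucocorticoid receptor targets stood out: 14 of 17 measured were higher early and none lower, with a median log2 fold change of 1.47, and the same 14 to 0 split held when adjusted over the list alone. Camera gave an adjusted p of 3.12e-25, and adjusted p = 4.52e-06 with an estimated correlation. Nfkbia, the inhibitor of NF-kappa B, was 6.86-fold higher. Of the 19 measured genes of glutamine, branched-chain amino acid and polyamine metabolism, 5 were higher and none lower, among them the transaminase genes Got1 (2.17-fold) and Gpt (1.68-fold). The call was adjusted p = 0.0133, or adjusted p = 0.0486 with an estimated correlation, and it did not pass under quantile normalization (adjusted p = 0.0821). Adjusted over the list alone, 5 were higher and 1 lower.

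The remaining early list calls were lost with an estimated correlation. Oxidative phosphorylation had 12 of 43 genes higher, such as Sdhc (1.68-fold) and Atp5f1a (1.37-fold), with adjusted p = 1.16e-10 and adjusted p = 0.0807 with an estimated correlation, and adjusted over the list alone 21 were higher. Glycolysis and glycogen had 8 of 20 higher, such as Eno3 (1.35-fold), Pfkfb1 (1.83-fold) and Gpd1 (2.14-fold, not past the threshold without 0 h replicate 4, at 0.82 on the log2 scale), with adjusted p = 0.0859 with an estimated correlation and 11 higher and 1 lower adjusted over the list alone. Atrophy and ubiquitin ligase genes had 5 of 14 higher, among them Foxo3 (2.65-fold) and Eif4ebp1 (2.73-fold), which codes for a repressor of translation, with adjusted p = 0.0505 with an estimated correlation and 6 higher adjusted over the list alone. Fatty acid uptake and oxidation had 6 of 21 higher, including the lipase gene Pnpla2 (2.74-fold) and Ucp3 (2.09-fold), with adjusted p = 0.44 with an estimated correlation and 6 higher adjusted over the list alone. Without 0 h replicate 2 that list had adjusted p = 0.182 and without 0 h replicate 3 adjusted p = 0.208, and Ucp3 did not pass without the latter, at 0.65 on the log2 scale. Triglyceride synthesis had 2 of 11 higher, Dgat2 (2.78-fold) and Lpin1 (2.57-fold), with adjusted p = 0.0807 with an estimated correlation, adjusted p = 0.0547 without 0 h replicate 4, and 2 higher and 1 lower adjusted over the list alone. Slow fibre genes (2 of 12 higher) and fast fibre genes (2 of 15 higher) both passed at adjusted p = 0.0133 but had adjusted p = 0.408 and adjusted p = 0.44 with an estimated correlation. Adjusted over the list alone these counts were 3 and 2. Slow fibre genes had adjusted p = 0.301 without 0 h replicate 2, fast fibre genes had adjusted p = 0.075 without 0 h replicate 1, and under quantile normalization neither passed and the fast fibre median changed sign. Fatty acid oxidation did not pass either under quantile normalization (adjusted p = 0.158), which left 7 lists in place of 10 and called proteasome subunits lower (adjusted p = 0.00233). Myogenic and neuromuscular junction genes were the 1 list called lower, with 6 of 11 lower and 1 higher. The acetylcholine receptor genes Chrnd (2.76-fold) and Chrna1 (2.52-fold) were lower and the myogenic regulator Myf6 was higher (2.24-fold), and the list had adjusted p = 0.114 with an estimated correlation and the same counts adjusted over the list alone. With the stricter signal filter that list did not pass (adjusted p = 0.413). Array weights left fatty acid oxidation (adjusted p = 0.325), slow fibre genes (0.11) and triglyceride synthesis (0.0636) not past the threshold.

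The late window, 72 to 168 h, was compared with control to describe the response from the third day on. The arrays labelled 168 h differed from those of 72 and 96 h, as given further on, so values without them, chosen after seeing the data, are set beside planned folds that they move by more than 1.5 times. Ddit4 was 30.1-fold higher (4.91 ± 0.27), Cebpd, by the probe set of larger change, 17.8-fold, Fkbp5 12.4-fold (3.63 ± 0.13) and Errfi1 10.8-fold. Ctdspl, a phosphatase gene, was 6.21-fold higher, Tinagl1 6.02-fold, the sulfotransferase gene Sult1a1 5.88-fold and Gnmt, glycine N-methyltransferase, 5.68-fold. The lowest gene was Rrad, a small GTPase, at 34.7-fold (-5.12 ± 1.02), although its 4 control arrays spread widely, at an intensity of 591 ± 510 (SD), and its change ran from -6.01 to -4.52 with each array left out in turn, farthest from the planned value without 0 h replicate 3. The larger Cebpd change ran from 3.08 to 4.69. Ifi27l2b was 6.85-fold lower, Myod1 5.83-fold, the matrix proteoglycan gene Lum 5.45-fold, Igfbp5 4.66-fold, the histone deacetylase gene Hdac4 4.59-fold, Tubb6 4.38-fold and the cytokine gene Il33 4.27-fold. The highest adjusted p among these 16 genes was 0.00108, for Cebpd. Without the 168 h arrays the log2 fold change was -3.53 for Lum (-2.45 in the planned window), -3.08 for Hdac4 (-2.20), -3.04 for Igfbp5 (-2.22), -5.83 for Rrad (-5.12) and 3.12 for Gnmt (2.51). By its brightest probe set Igfbp5 stood at -1.84 in the planned window and at -2.68 without the 168 h arrays. The dimmer side lay below the filter intensity for Ddit4, Tinagl1 and Cebpd as before, for Gnmt (12.8 in control), and for the late mean of Rrad (10.8), Hdac4 (33.7) and Ifi27l2b (37.4).

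Trim63 was 3.53-fold higher late (1.82 ± 0.25, adjusted p = 1.16e-06), Glul 3.47-fold, Klf15 3.25-fold and Per1 4.01-fold, and Nr3c1 was 1.81-fold lower. Col1a1 was 4.37-fold lower (-2.13 ± 0.32, adjusted p = 5.62e-06) and Col3a1 3.3-fold lower, and without the 168 h arrays these values were -3.27 and -2.77 on the log2 scale. Mstn passed the threshold without the 168 h arrays, at -1.07, and not with them, at -0.52 ± 0.31, and its lower value at 72 h alone did not pass without 0 h replicate 3 (-0.80). Fbxo32 likewise stood at 1.39 without and 0.64 ± 0.49 with them. Foxo1 was 2.22-fold higher but did not pass without 0 h replicate 1 (log2 1.10) or 0 h replicate 4 (1.03). Without 0 h replicate 3, Pdk4 (3.41-fold) and Mt2A (3.14-fold) did not pass, at 1.22 and 0.90, and without 0 h replicate 2 Tsc22d3 (1.91-fold) did not, at 0.86. Odc1 (0.16 ± 0.14) did not pass, and neither did the brighter probe set of Igf1 (-0.73 ± 0.41), while the other was lower (-0.81, adjusted p = 0.000989).

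Late against control, 1596 probe sets passed, 620 higher and 976 lower. Without the 168 h arrays 2255 passed, 878 higher and 1377 lower, and with each array centred on its median the planned split turned to 851 higher and 546 lower, 60.9% higher in place of 38.8%. Without the 4 arrays of high 3′ to 5′ ratio, 1331 passed.

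Late list calls that held with an estimated correlation were 4. Receptor targets had 13 of 17 higher and none lower, as many adjusted over the list alone, with adjusted p = 5.14e-05 with an estimated correlation. Collagen and extracellular matrix had 23 of 38 lower and none higher, with a median of -0.61, and 26 lower adjusted over the list alone, such as Fn1, fibronectin (2.65-fold, and log2 -2.04 without the 168 h arrays against -1.41). Camera gave adjusted p = 2.2e-12 and adjusted p = 0.0164 with an estimated correlation, and without the 168 h arrays 28 were lower with a median of -1.05. Myogenic and neuromuscular junction genes had 7 of 11 lower, as many adjusted over the list alone, including the transcription factor gene Runx1 (3.84-fold) and Chrna1 (3.19-fold). That list had adjusted p = 0.0407 with an estimated correlation, adjusted p = 0.135 with it once the 168 h arrays were left out, and adjusted p = 0.0617 with the stricter signal filter. Genes of glutamine, branched-chain amino acid and polyamine metabolism had 5 of 19 higher and 1 lower, and 6 higher and 1 lower adjusted over the list alone. They had adjusted p = 0.033 with an estimated correlation, adjusted p = 0.107 with it without the 168 h arrays, and did not pass under quantile normalization. Gpt was 2.13-fold higher and Sms, spermine synthase, 1.66-fold lower.

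Of the other late list calls, antigen presentation and interferon response had 8 of 16 lower and 1 higher, and 9 lower and 1 higher adjusted over the list alone, such as the class II genes RT1-Da (2.28-fold) and Cd74 (1.7-fold). That list had adjusted p = 0.14 with an estimated correlation. Slow fibre genes had 5 of 12 higher, and 6 adjusted over the list alone, such as Myoz2 (2.51-fold) and Csrp3 (2.48-fold, and log2 2.15 without the 168 h arrays against 1.31), with adjusted p = 0.081 with an estimated correlation. Fatty acid uptake and oxidation had 7 of 21 higher and 1 lower, and 8 higher and 1 lower adjusted over the list alone, such as Pnpla2 (4.51-fold), Acadm (1.53-fold) and Lpl (1.78-fold), with adjusted p = 0.106 with an estimated correlation. Oxidative phosphorylation had 12 of 43 higher, and 16 adjusted over the list alone, with adjusted p = 0.0976 with an estimated correlation. Atrophy and ubiquitin ligase genes had 5 of 14 higher and 1 lower, as many adjusted over the list alone. Glycolysis and glycogen had 3 of 20 higher, and 5 adjusted over the list alone. Triglyceride synthesis had 4 of 11 higher and 1 lower, as many adjusted over the list alone. These last lists had adjusted p = 0.123, 0.22 and 0.081 with an estimated correlation, and none of them passed under quantile normalization. Triglyceride synthesis did not pass without 0 h replicate 4 (adjusted p = 0.0591), 72 h replicate 4 (adjusted p = 0.0535) or 96 h replicate 2 (adjusted p = 0.056). Without the 168 h arrays neither it (adjusted p = 0.0636) nor glycolysis (adjusted p = 0.0752) passed.

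**Figure D2:**
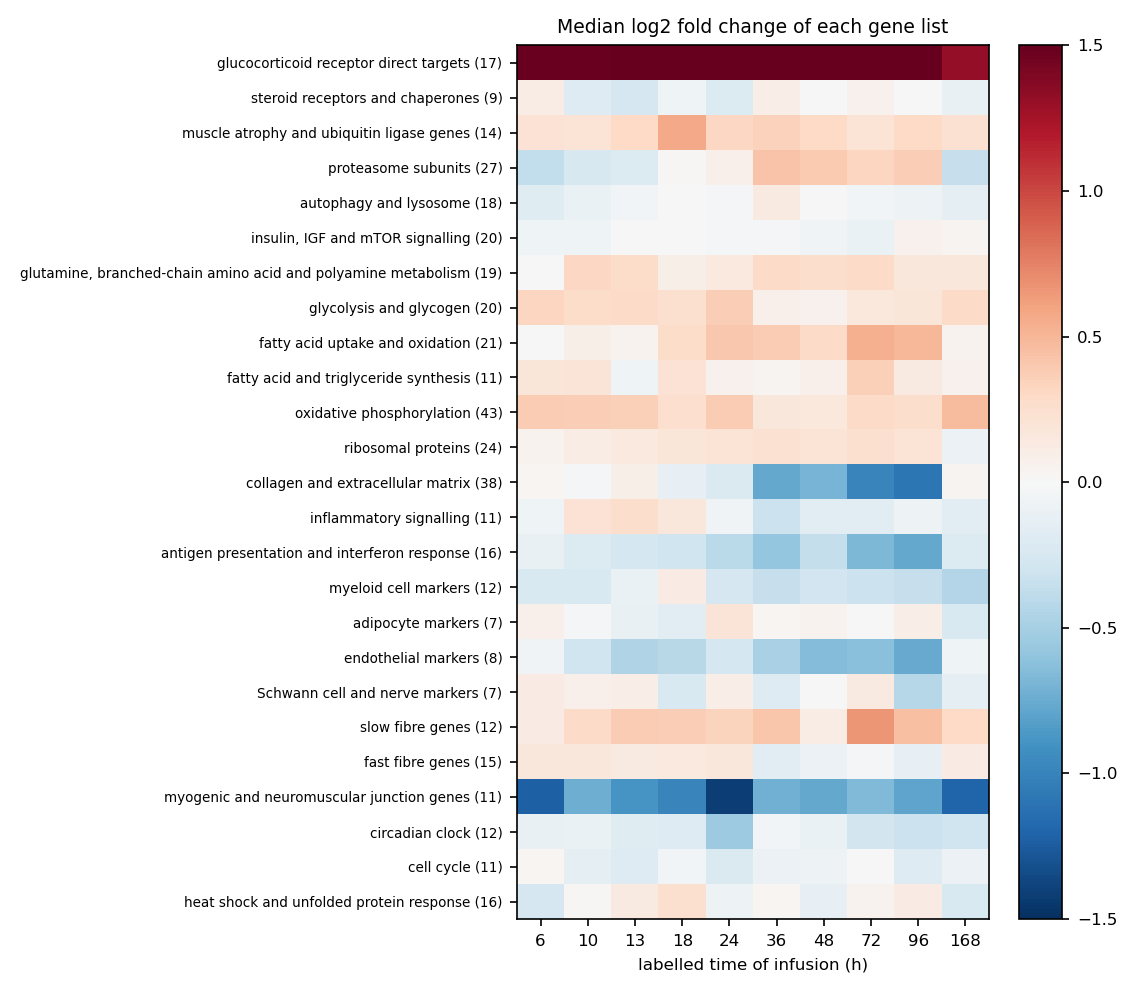
Median log2 fold change against 0 h (colour, scale ending at ±1.5) of the measured genes of 25 lists (rows, number of genes in brackets) at each labelled time in hours (columns). Receptor targets are high at every time, and the collagen and extracellular matrix list moves from 0.03 at 6 h to -1.08 at 96 h and stands at 0.04 at 168 h.

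Late was compared directly with early to ask which responses changed with continued infusion. The control means do not enter this contrast, although the control arrays enter the shared variance and the signal filter. Higher late were Arg2, a mitochondrial arginase (3.74-fold, 1.90 ± 0.24), Pla2g2a (2.92-fold), the haemoglobin gene Hbb (2.76-fold), Tmem229b (2.62-fold), the oxygen-sensing hydroxylase gene Egln3 (2.56-fold), Sqor, which oxidises sulfide (2.48-fold), Chac1, which degrades glutathione (2.46-fold), and Sgsm3 (2.36-fold). Lower late were Rrad (18.6-fold), the matrix genes Postn (6.8-fold), Mfap4 (5.67-fold), Col1a1 (4.87-fold) and Col1a2 (4.82-fold), Nrep (5.05-fold), the calcium buffer gene Pvalb (4.83-fold) and Mstn (4.8-fold, -2.26 ± 0.21). Mstn lay below all 16 early arrays on 10 of 12 late arrays, Col1a1 on 8 of 12 and Rrad on 0 of 12. The highest adjusted p among these 16 genes was 0.0104, for Hbb. Without the 168 h arrays most of these changes were larger. On the log2 scale, the value without them and the planned one were 3.23 and 1.55 for Pla2g2a, 2.85 and 1.90 for Arg2, 2.58 and 1.39 for Tmem229b, 2.03 and 1.30 for Chac1, and 2.02 and 1.31 for Sqor. Among the lower genes they were -4.93 and -4.21 for Rrad, -4.31 and -2.76 for Postn, -4.17 and -2.50 for Mfap4, -3.83 and -2.34 for Nrep, -3.60 and -2.27 for Col1a2, -3.43 and -2.28 for Col1a1, and -3.14 and -2.27 for Pvalb. The dimmer side lay below the filter intensity for the early mean of Arg2 (37.4), Tmem229b (35.4), Sgsm3 (24.7) and Pla2g2a (16.8), and for the late mean of Mfap4 (30.4) and Rrad (10.8). Glul by its brightest probe set (1.37-fold) and Klf15 (1.48-fold) were higher late and Fkbp5 was lower (1.31-fold, adjusted p = 0.00177). Against control, another Glul probe set stood at a log2 fold change of 1.99 early and 1.86 late, so it was not higher late. A further one stood at 1.54 early and 1.96 late. Trim63 differed by 0.12 ± 0.17 and Nr3c1 by 0.08 ± 0.11 on the log2 scale, neither past the threshold.

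In this comparison 1225 probe sets passed, 511 higher and 714 lower late. Without the 168 h arrays 2393 passed, 1049 higher and 1344 lower, and with median centring the planned split was 609 higher and 434 lower, 58.4% higher in place of 41.7%. Array weights gave 1974.

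Collagen and extracellular matrix was the list call of late against early that held with an estimated correlation (adjusted p = 7.73e-05, and 2.47e-30 with the preset one). In it, 28 of 38 genes were lower and none higher, and 31 lower adjusted over the list alone, with Col6a3 2.09-fold and Col3a1 3.59-fold lower (log2 -1.73 and -2.89 without the 168 h arrays, against -1.06 and -1.84). The median of the list was -0.71, and -1.06 without the 168 h arrays. Proteasome subunits had 10 of 27 higher and none lower, such as Psmd1 (1.53-fold), Psma7 (1.43-fold) and Psmc5 (1.39-fold), and 16 higher adjusted over the list alone. That call had adjusted p = 1.73e-09 and adjusted p = 0.276 with an estimated correlation, and 19 of 27 were higher without the 168 h arrays. Fatty acid uptake and oxidation had 4 of 21 higher and 1 lower, and 6 and 2 adjusted over the list alone, such as Acadl (1.41-fold), with adjusted p = 0.321 with an estimated correlation. Slow fibre genes had 5 of 12 higher, as many adjusted over the list alone, with adjusted p = 0.276 with an estimated correlation. Lower late were fast fibre genes (5 of 15, and 7 adjusted over the list alone), antigen presentation (5 of 16, and 5 lower with 1 higher adjusted over the list alone), inflammatory signalling (5 of 11 with 1 higher, as many adjusted over the list alone) and endothelial markers (2 of 8, and 4 adjusted over the list alone). They had adjusted p = 0.297, 0.321, 0.276 and 0.276 with an estimated correlation. Antigen presentation did not pass without the 4 arrays of high 3′ to 5′ ratio (adjusted p = 0.148), and inflammatory signalling did not pass with array weights (adjusted p = 0.0604).

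The times that are multiples of 24 h were compared with control because they share its clock time if the labelled hours are exact and all infusions began at the clock time of the control sampling. The clock time of sampling is not given. In that comparison 1727 probe sets passed, 677 higher and 1050 lower, and 2130 passed without the 168 h arrays. The share of higher calls was 39.2%, 62.3% with median centring and 49.5% with quantile normalization. Receptor targets had 13 of 17 higher with a median of 1.71, and matrix genes 19 of 38 lower and 1 higher with a median of -0.61, and 13 higher and 24 lower in these lists adjusted over the list alone. They had adjusted p = 4.51e-05 and adjusted p = 0.039 with an estimated correlation. The other list calls, 9 in number, had adjusted p of 0.0624 or more with an estimated correlation.

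At single times the number of probe sets past the threshold was 492 at 6 h, 708 at 10 h, 690 at 13 h, 899 at 18 h, 913 at 24 h, 1082 at 36 h, 1199 at 48 h, 1579 at 72 h, 1701 at 96 h and 651 at 168 h. At 6 h the farthest genes were Rasd1 (37.1-fold higher) and Ddit4 (24.1-fold higher), with Osgin1 (11-fold lower) and Myod1 (9.85-fold lower). At 10 h Fkbp5 was 18.1-fold higher and Pla2g2a 12.4-fold lower, at 13 h Marcks was 6.78-fold lower, and at 18 h Dbp was 9.22-fold lower. At 24 h Ddit4 was 28.8-fold higher and Ifi27l2b 6.83-fold lower. Lum was 11.6-fold lower at 36 h, Mfap4 9.39-fold lower at 48 h and 23.2-fold at 96 h, and Postn 19.9-fold lower at 72 h. Rrad was the lowest named gene from 24 h to 96 h, at 20.4-fold at 24 h, 27.9-fold at 36 h, 59.1-fold at 48 h, 38.8-fold at 72 h and 83.6-fold lower at 96 h. Some of these sizes moved by more than 1.5 times with 1 array left out: Rasd1 at 6 h (log2 4.79 to 5.82) and 168 h (5.14 to 6.16), Dbp at 18 h (-3.68 to -2.57), Postn at 72 h (-4.94 to -3.20), and Rrad at every time given, such as 96 h (-7.28 to -5.79). The arrays left out that moved them farthest were 0 h replicate 2 for Rasd1, 18 h replicate 2 for Dbp, 72 h replicate 2 for Postn and 0 h replicate 3 for Rrad, with 36 h replicate 1 for Rrad at 36 h. The dimmer side lay below the filter intensity for Rasd1 and Ddit4, and at the times given for Osgin1 (14.8), Myod1 (32.4 at 6 h and 24.4 at 168 h), Pla2g2a (6.12 at 10 h and 4.71 at 168 h), Dbp (19.3), Ifi27l2b (37.6), Postn (18.6), Mfap4 (18.7 at 48 h and 7.55 at 96 h) and Rrad (18.3 or less). At 168 h the farthest genes were Rasd1 (47-fold higher), Ddit4 (31.5-fold higher), Pla2g2a (16.1-fold lower) and Myod1 (13.1-fold lower). The 6 h count was 317 without 0 h replicate 1, 270 without 0 h replicate 4 and 266 without 6 h replicate 4, and the 168 h count was 415 without 0 h replicate 4. Median centring raised the share of higher calls by more than 10 points at every time but 6 h. It went from 49.6% to 61.9% at 10 h, from 48.4% to 65.4% at 13 h, from 44.5% to 56.4% at 18 h, from 44.9% to 65.1% at 24 h and from 40% to 67.7% at 36 h. At the later times it went from 41.1% to 61.8% at 48 h, from 39.5% to 55.6% at 72 h, from 39.1% to 59.6% at 96 h and from 49.3% to 71.6% at 168 h. At 36 h the share was 50.8% with quantile normalization, and the median log2 fold change of all tested probe sets was -0.0403 as deposited and 0.111 with median centring. Fits of only the 2 groups compared gave fewer calls at every time, from 87 at 6 h to 690 at 96 h.

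**Figure D3:**
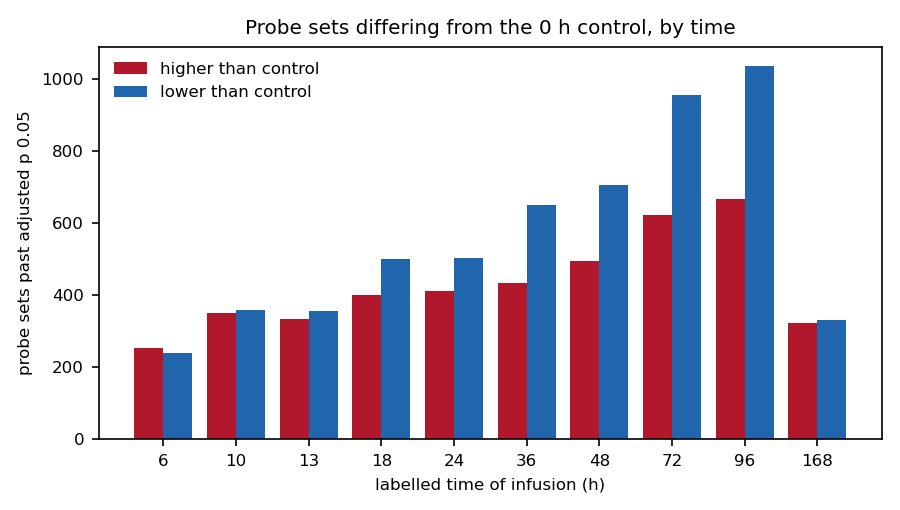
Number of probe sets past an adjusted p of 0.05 against the 0 h control (vertical axis) at each labelled time in hours (horizontal axis), higher in red and lower in blue. At 96 h there were 665 higher and 1036 lower, and at 168 h 321 higher and 330 lower.

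The groups were also compared pair by pair, a choice made after seeing the data. By limma, no probe set passed between 6 h and 168 h, with 252 of 9520 at an unadjusted p below 0.05, while 1400 passed between 72 h and 168 h and 1530 between 96 h and 168 h. Between 72 and 96 h no probe set passed, with 184 at an unadjusted p below 0.05. Against the mean of 72 and 96 h, 1023 probe sets were higher and 946 lower on the arrays labelled 168 h. The genes that follow were picked after their values were seen. Rasd1 stood at a log2 fold change from control of 5.21 at 6 h, 0.79 at 96 h and 5.55 at 168 h (SE 0.45), and Mrpl41 at 2.73, 0.72 and 3.01 (SE 0.30). The kinase gene Sgk1, a receptor target, stood at 1.53, -0.98 and 1.32 (SE 0.34). Col1a1 stood at -3.64 at 96 h and 0.16 at 168 h (SE 0.39), and Arg2 at 3.61 and 0.12 (SE 0.45). Fkbp5, Ddit4 and Errfi1 stood at 3.63, 4.98 and 3.23 at 168 h.

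**Figure D4:**
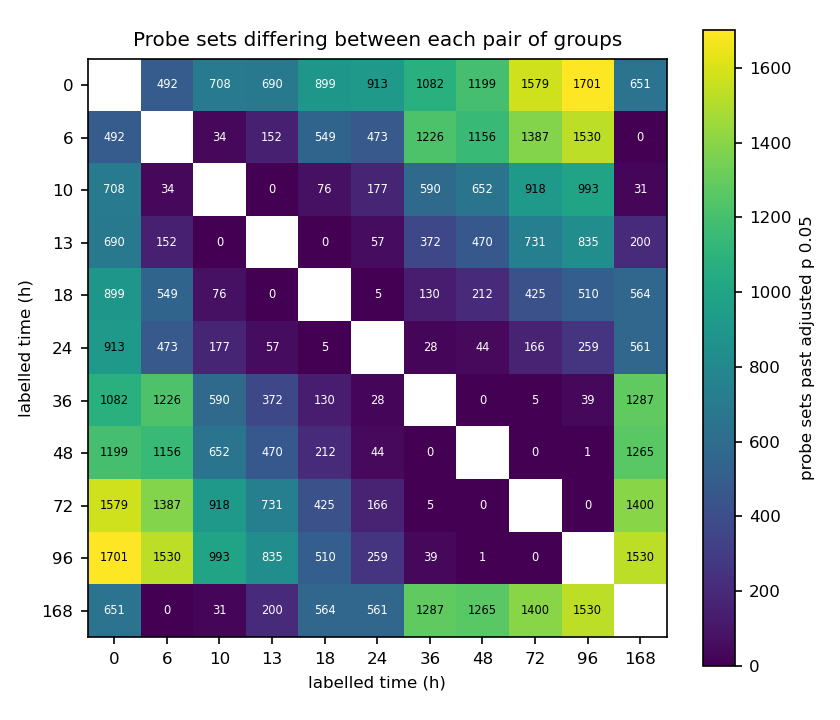
Number of probe sets past an adjusted p of 0.05 (colour and digits) between each pair of groups, with labelled times in hours on both axes. Neighbouring times from 6 h to 96 h differ in at most 34 probe sets and the 0 h and 6 h groups in 492, and between the 168 h group and the 6 h group 0 pass, against 1530 between 168 h and 96 h.

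Lists of other cell types were measured alongside. Endothelial markers had 4 of 8 lower and 1 higher late, and 5 lower and 1 higher adjusted over the list alone, Vwf (1.62-fold), Cldn5 (2.34-fold) and Kdr (2.26-fold) among the lower and Flt1 higher (2.19-fold), without a list call against control (adjusted p = 0.132). Myeloid markers had 3 of 12 lower late, as many adjusted over the list alone, and no list call (adjusted p = 0.152), although without 0 h replicate 3 the list passed (adjusted p = 0.0271). Cd68 was 2.05-fold lower, but not past the threshold without 0 h replicate 2 (log2 -0.83) or without the 4 arrays of high 3′ to 5′ ratio (-0.82). Fcer1g was 1.69-fold lower, but not past it without these 4 arrays (-0.47). No adipocyte marker of 7 passed late. Of 7 Schwann cell and nerve markers, Cnp was 1.56-fold lower, but not past the threshold without 0 h replicate 2 (-0.42) or without these 4 arrays (-0.48). Of 4 lymphocyte markers, none passed. Of 3 erythroid markers, Hbb (2.76-fold) and Hba-a3 (log2 0.61 ± 0.19) were higher late than early.

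The other lists were not called in any of the 3 window comparisons. Late against control, 1 of 9 steroid receptor and chaperone genes was higher and 2 were lower, as many adjusted over the list alone. Of 18 autophagy and lysosome genes 4 were higher and 1 lower, and 5 higher and 1 lower adjusted over the list alone (Bnip3 1.73-fold and Gabarapl1 2.33-fold higher, Ctsb 1.89-fold lower). Of 20 insulin, IGF and mTOR genes 4 were higher and 2 lower, and 5 higher and 4 lower adjusted over the list alone (the glucose transporter gene Slc2a4 3.08-fold higher). The median and the mean of these 3 lists differed in sign late, at -0.07 and 0.24, -0.14 and 0.07, and -0.09 and 0.25, and early, at -0.24 and 0.21, -0.05 and 0.01, and -0.11 and 0.26. Signs also differed for adipocyte markers late (-0.03 and 0.05), and early for matrix genes (-0.05 and 0.00) and Schwann cell markers (0.06 and -0.07). For late against early they differed for autophagy (-0.03 and 0.06), insulin signalling (0.10 and -0.01), oxidative phosphorylation (-0.01 and 0.00) and the clock (-0.07 and 0.03). The test pointed up while the median was -0.01 for heat shock genes late and for cell cycle genes late against early. Of 24 ribosomal protein genes 1 was lower and none adjusted over the list alone, of 11 cell cycle genes 1 was lower (Ccnd1, 2.52-fold), and of 16 heat shock and unfolded protein genes 2 were higher and 1 lower, and 2 higher and 2 lower adjusted over the list alone. Of 12 clock genes, 3 were higher and 4 lower, as many adjusted over the list alone, with Nfil3 2.68-fold and Bmal1 1.5-fold higher. Bhlhe41 was 1.78-fold lower, but not past the threshold without 0 h replicate 3 (-0.51).

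Some of these lists passed with the preset correlation when 1 array was left out. Proteasome subunits, not called against control, were called higher late without 0 h replicate 1 (adjusted p = 0.00737), 0 h replicate 4 (0.00186), 72 h replicate 1 (0.0365), 96 h replicate 3 (0.0498) or 168 h replicate 4 (0.0431). They were called lower early without 0 h replicate 2 (adjusted p = 9.75e-06), 6 h replicate 3 (0.0409), 10 h replicate 1 (0.0375) or 10 h replicate 4 (0.0432). Ribosomal proteins were called higher early without 0 h replicate 1 (0.0285), 0 h replicate 3 (0.0224), 0 h replicate 4 (0.0196) or 6 h replicate 2 (0.0359), and late without 0 h replicate 3 (0.0391), 0 h replicate 4 (0.0486) or 168 h replicate 4 (0.0114). Myogenic and neuromuscular junction genes were called lower late than early without 10 h replicate 4 (0.0463), 13 h replicate 1 (0.0447), 18 h replicate 1 (0.0411), 72 h replicate 4 (0.0433), 96 h replicate 1 (0.0393) or 168 h replicate 1 (0.0334). Without all 168 h arrays proteasome subunits (6.03e-05, and adjusted p = 0.373 with an estimated correlation) and ribosomal proteins (0.0247, and adjusted p = 0.569 with an estimated correlation) were called higher late. Of 24 ribosomal protein genes 0 were higher and 1 was lower in that fit. Without the 4 arrays of high 3′ to 5′ ratio, inflammatory signalling was called higher early (0.0303), proteasome subunits lower early (8.93e-06) and ribosomal proteins higher late than early (0.0447). The same fit lost the early calls of fatty acid oxidation (0.168), triglyceride synthesis (0.0598) and slow fibre genes (0.3).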

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

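All tests of why the arrays labelled 168 h resembled the 6 h arrays were chosen after the result was seen, while the counts over other splits of the arrays were planned.

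Within groups of 4 arrays, values far from the other 3 were sought for the signal of named genes and for the log2 ratio of 3′ to 5′ GAPDH signal. Of 233 groups tested, 23 held such a value (9.87%), and chance alone gives about 1 in 20. In the control group, 0 h replicate 2 stood apart for Cebpd at a log2 signal of 7.609, Ddit4 at 4.768, Mrpl41 at 9.5 and Marcks at 8.869, and 0 h replicate 4 for Sgsm3 at 6.946. At 13 h, replicate 2 stood apart for Foxo1 at 8.539, Per1 at 5.236 and the GAPDH ratio at 0.1699, and replicate 4 for Mstn at 7.715. At 18 h, replicate 2 stood apart for Col3a1 at 10.66, replicate 1 for Igf1 at 5.906 and replicate 3 for Pdk4 at 10.56. Single values stood apart for Per1 on 24 h replicate 4 at 5.066, Trim63 on 36 h replicate 4 at 10.76, Tsc22d3 on 72 h replicate 4 at 9.591 and Col1a1 on 96 h replicate 1 at 8.229. On 96 h replicate 4 they were Cebpd at 8.963, Fbxo32 at 6.131, Tsc22d3 at 9.725 and the GAPDH ratio at 0.5794. On 168 h replicate 4 they were Fbxo32 at 3.612, Pdk4 at 8.208 and the GAPDH ratio at 1.429. Each of the 4 arrays of high GAPDH ratio held at least 1 such value, and no cause was tested for single values.

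The treated groups differed from each other. Between the late and the early window 1225 probe sets differed by limma, and 1969 differed between the arrays labelled 168 h and the mean of 72 and 96 h. On a line from the 6 h mean at 0 to the 96 h mean at 1, the treated groups up to 72 h lay in the order of their labels on average over both pairs of replicates. Within a pair, 36 h (0.853) lay beyond 48 h (0.832) in replicates 3 and 4. The 168 h group lay at -0.1 (-0.154 to -0.0465). With each array left out of its own group mean, 3 of 4 arrays of 6 h were nearest to the 168 h group, and 2 of 4 arrays labelled 168 h were nearest to 6 h.

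An ended infusion with a return to control is argued against by 54 probe sets changed 2-fold or more at every time from 6 to 96 h, whose 168 h change was 0.822 of that at 96 h in the median (quartiles 0.661 to 1.03). For a fading of later responses alone, probe sets past the threshold at 6 h that had moved back toward or past control by 72 and 96 h were taken. Of these 180, 86 were higher than control at 6 h. At 168 h 91.1% of them (164 of 180) lay nearer to the 6 h mean, which the prediction had counted against fading. Where values had gone farther past control than they stood at 6 h, fading to control also ends nearer the 6 h mean. How many did so was not counted, so this share does not settle the question. All 180 had passed against control at 6 h, and at control again by 168 h they would differ from 6 h likewise. By limma, no probe set passed between 6 h and 168 h, with 252 of 9520 at an unadjusted p below 0.05. For these 180 probe sets that argues against fading to control alone. A swap of labels between these groups cannot account for the likeness, since an exchange of names leaves the 2 groups as alike. The 1530 probe sets between 6 h and 96 h do not tell whether one took place, since the arrays labelled 168 h differed from 96 h in as many. The remaining label error, 1 wrong time label on the whole 168 h group, stays open. The position of -0.1 restates the likeness, and the control group, at 0.179, also lay near the 6 h end. A renewed early response on the seventh day, such as one to a new pump or to handling, stays open and was not tested.

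Other splits of the same arrays into groups of the same sizes were counted, 100 for the windows and 35 for each time, the real split included. The real split gave the highest count for the change at any time (2455 against a highest other of 49, 1 of 100 splits as large) and early against control (1126 against 496, 1 of 100). The same held for late against early (1225 against 15, 1 of 100) and the multiples of 24 h (1727 against 1407, 1 of 100). These shares are not adjusted over the comparisons. Other splits also mix times within a group, which adds to the residual spread and lowers their counts, so the shares are no exact measure of chance. For late against control (1596) 3 of 100 splits were as large, the real one included, so chance is not excluded there. The highest other gave 1855, with 0 h replicate 2 and 168 h replicates 2, 3 and 4 on one side. At each single time the real split gave the highest count, 1 of 35. That is the smallest share 35 splits can give and is not adjusted over the 10 times, so chance is not excluded for any single time alone. The real count and the highest other were 492 and 284 at 6 h, 708 and 163 at 10 h, 690 and 96 at 13 h, 899 and 322 at 18 h, 913 and 35 at 24 h, 1082 and 193 at 36 h, 1199 and 312 at 48 h, 1579 and 255 at 72 h, 1701 and 548 at 96 h, and 651 and 623 at 168 h. For the number of lists called, 4 of 100 splits were as large early (10 against a highest other of 11) and 3 of 100 late (11 against 13). For late against early 9 of 100 were (8 against 11). Without adjustment over the comparisons, chance is not excluded for these numbers. The median number of lists called over the other splits was 4 early, 6 late and 4 for late against early, so list calls with the preset correlation also arise without the real grouping.

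A split of the control and late arrays chosen after seeing the data points to a structure of the samples. The 4 arrays of high 3′ to 5′ ratio against the other 12 gave 3580 probe sets, more than the 1596 of the real comparison. Without these 4 arrays the late comparison gave 1331.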

How the results depend on the processing

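The fits without the 168 h arrays and without the 4 arrays of high 3′ to 5′ ratio were chosen after seeing the data, and the other alternatives were planned. No gene or list past the threshold was past it in the opposite direction under any of them. The side that held most calls did change with median centring. Counts went from 523 higher and 603 lower to 574 and 392 early, and from 620 and 976 to 851 and 546 late. For late against early they went from 511 and 714 to 609 and 434. Some list medians changed sign as their calls were lost, such as that of fast fibre genes early under quantile normalization. Of the counts, 451 stayed within 1.5 times the value as reported and 27 moved further. Of values for single genes, 8900 kept their side of the threshold, 362 lost it and 6 gained it. List members not past the threshold were left out of this tally, and many genes had been named for large changes past it. The tally therefore left little room for gains and favoured kept calls. Of list results, 2447 kept their side, 53 lost it and 41 gained it.

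With array weights, 3918 probe sets differed at any time, 1974 between late and early, 845 at 6 h, 1194 at 10 h and 1318 at 168 h. The cause was not tested. Quantile normalization left 7 lists late against control in place of 11, and an estimated correlation left 2 lists early, 4 late and 1 for late against early. An estimated correlation above the preset one widens a list's error by construction. With the series of original sample numbers as a block, 739 probe sets passed at 6 h, and the cause was not tested.

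Fits of only the 2 groups compared gave 87 at 6 h, 288 at 10 h, 311 at 13 h, 343 at 18 h, 310 at 24 h, 538 at 36 h, 409 at 48 h, 623 at 72 h, 690 at 96 h and 133 at 168 h. They use 8 arrays in place of 44 and take the spread from the 2 groups alone. A wider spread in the control group therefore weighs more in them, and these 2 causes of lower counts were not told apart. Without the 168 h arrays, 2393 probe sets differed between late and early, where the late window lost a group unlike the other pair. Without the 4 arrays of high ratio, 759 passed at 6 h, and the cause was not tested.

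With each array left out in turn, early against control gave 726 to 1213, 6 h gave 266 to 722 and 168 h gave 415 to 869. Each fit has fewer samples, but which array was left out also mattered, since counts rose as well as fell. The other counts stayed within 1.5 times, such as 2303 to 2597 at any time, 1212 to 1817 late and 1017 to 1234 for late against early.

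Arrays of the same replicate number correlated at 0.170 on average after removal of group means (lowest -0.54, 153 of 220 above 0.1), against -0.052 for different numbers, and 34 of 44 arrays, not all, correlated best with their own number. The labels give different rats at each time, and not every correlation was above 0.1. Something common to a replicate number requires neither the same rats nor that every pair be above 0.1. Removal of group means by itself tends to bring the value for different numbers below 0 when that for equal numbers is above it. The original sample numbers run in series over the times, and arrays of one series correlated at 0.186 on average (163 of 220 above 0.1). The correlation is a hint from the data of something common to a series or replicate number, and what it was is not known. The comparisons of every pair of groups, 6 h against 168 h among them, were run without a block. With the replicate number as a block, 3125 probe sets differed at any time, 1422 early, 1984 late and 1535 between late and early, and 10 lists were called late in place of 11, as triglyceride synthesis did not pass (adjusted p = 0.0503). Probe sets below an intensity of 42.4 were not tested.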

Other observations

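The test of clock transcripts was chosen after its result was seen. The fall of matrix transcripts was picked from the results, and the predictions for its tests were written before these were run.

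Myostatin was higher at 10 h, at a log2 fold change of 2.02, and that call held without each array of these groups (1.75 to 2.53). Its call at 72 h (-1.30, SE 0.38) did not hold without 0 h replicate 3 (-0.80, adjusted p = 0.131) or without 72 h replicate 1 (-1.11, adjusted p = 0.0658), so a fall below control is not settled. Glutamine synthetase (Glul) was higher at 96 h (2.33, SE 0.22). At 6 h (0.77) and 168 h (0.75) this brightest probe set also passed, but not without certain single arrays, such as 0 h replicate 2 (0.46 and 0.44). Another Glul probe set was changed 2-fold or more at every time from 6 to 96 h, and stood at 1.33 at 168 h.

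Collagen and matrix transcripts were lower at 72 and 96 h. RNA quality of the arrays of high 3′ to 5′ GAPDH ratio, as the whole cause, is argued against by a median of -1.12 over the matrix list without these arrays, and -1.05 with them. The control arrays kept in that fit had beta-actin log2 ratios of 0.55 to 1.07, and the kept 72 and 96 h arrays at most 0.49. A difference in RNA quality between these groups was not tested. A lower share of fibroblasts stays open. The matrix list changed by a mean of -1.28 (28 of 38 lower) and 18 measured fibroblast markers by -0.50 (9 of 18 lower), a difference of -0.786 with an exact two-sided permutation p of 0.00202 over 495 splits of the arrays. The prediction had counted such a difference against a lower share, but it took all markers as alike, and they moved apart. Anxa2 (-1.40), Pdgfra (-1.15) and Lgals1 (-1.10) fell as far as the median of the matrix list, and Medag (-0.93), Ddr2 (-0.91), Cd55 (-0.87) and Fap (-0.81) fell nearly as far. Vim stood at -0.49, Axl at -0.06 and Gsn at 0.22, and how much of each marker comes from other cells was not measured. An effect of the infusion on matrix transcripts stays open too, and the design does not part it from time since surgery.

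Clock transcripts were away from control at several times. If sampled at the same clock time, which is not given, the groups at 24, 48, 72 and 96 h would be alike at an unshifted phase. However, 5 of 12 clock probe sets differed among them: Bmal1 (adjusted p = 0.00216), Bhlhe41 (0.0141), Nr1d2 (0.0141), Dbp (0.038) and Nr1d1 (0.0425), by limma adjusted over the list alone. Only under that condition does this argue against time of day at an unshifted phase as the whole cause. A shift of the clock by the drug stays open, but a shift that stayed constant over these times would leave the groups alike too, so the test does not point to one. Without vehicle groups at the same times, a shift by surgery or handling also stays open and was not tested. Other causes of a changed level of these transcripts were not tested either. At 24, 48, 72 and 96 h Bmal1 stood at log2 fold changes of 1.36, 0.57, 0.55 and 0.66, and Dbp at -1.85, -0.38, -0.43 and -1.34.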
